A study of Mus musculus with 2 samples.

How the data were processed

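Total RNA of whole mouse embryos at embryonic day 10.5 was extracted with TRI reagent and sequenced on an Illumina instrument from standard libraries, per the labels' protocols. The labels name TopHat and the mouse genome build mm9, per the submitters' processing notes, without a version. The read counter, the read filters and whether strand was used are not given in the sources used here, so a gene and its antisense partner cannot be told apart. Each of the 2 files gave, per locus, RPKM values and read counts as the authors deposited them, per the file headers: RPKM is reads per kilobase of transcript and library size, and the counts are whole numbers that were not normalized. The design had assumed RPKM alone, so RPKM stayed the main unit. The counts served for depth, counting error and an alternative in CPM, counts scaled to their sum over loci in each library. No count test was run, as there is only 1 group.

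The files held 34676 rows of Ensembl identifiers. Rows with the same set of gene identifiers were summed, which gave 34624 loci, of which 2473 (7.14%) joined several gene identifiers. Symbols were matched by identifier from a table of names, and 32642 of 37681 identifiers (86.6%) had one. Gene types came from a later annotation on another build and were used as classes only, with no coordinates. The reads per RPKM had the same ratio between replicates (5.68, within 1 percent) in 100.0% of single-transcript loci with over 200 reads in replicate 1 but in 23.2% of multi-transcript loci, so the length behind the authors' RPKM differed by library for many loci. Loci with 1 to 2 RPKM had a median of 18 reads in replicate 1 and 106 in replicate 2, so low values of replicate 1 are the less precise.

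Before the data were examined, 51 gene lists (790 entries, 737 genes), 32 gene pairs, the tests and the rule for named genes were fixed. Named genes were the 20 highest loci, the 3 highest and the lowest member of each list with any member at 0 in both replicates, the pair genes, all Hox genes, and the 10 largest log2 ratios each way between replicates with a mean of 1 RPKM or more. Highest and lowest are by the mean RPKM of both replicates. Some genes that the rule allows are not named. Of the list genes, 728 had a locus and 9 did not (Ahsp, Hoxd4, Sox1, Rian, Mirg, Snrpn, Kcnq1ot1, Snhg1 and Gdf1, not analysed here), and 128 lay in joined loci. List statistics used distinct loci.

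Levels are given as RPKM in replicate 1 and then replicate 2, and log ratios are on the log2(RPKM + 1) scale, which understates differences of low genes. A locus was called detected at 1 RPKM or more in both replicates. A list's median level was placed among 10000 random lists of the same size, and its median log2 ratio between replicates among 10000 random lists matched on mean RPKM in 20 bins, as descriptions of these 2 libraries. Of the 51 lists, 17 had a median level above the 97.5th percentile of random lists and 2 below the 2.5th. A pair was called beyond the replicate spread when both replicates had the same sign and the mean was over 2 SD of the log2 ratio of loci of that level, and 17 of 32 pairs were. Loci of 221 RPKM or more formed 1 level group with an SD of 1.19, as it also held the small RNAs that differed most. Its limit of 2.39 is thus wide for Hbb-y against Hbb-bh1, Ldha against Ldhb and Crabp1 against Crabp2, all called within. The trend of Hox levels with paralogue number was tested with 100000 permutations of levels within clusters, two-sided. With 2 replicates no test between pair members could give a two-sided exact p below 0.333.

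The methods were tested on simulated data. All of 200 loci changed 4-fold were called at 2-fold (100%) with 0.0331% of the 18150 unchanged loci of 1 RPKM or more. The SD of the log2 ratio was recovered as 0.29 for a simulated 0.3 over loci of 10 RPKM or more. The list test placed 5.7% of 1000 unchanged lists of 15 loci outside the middle 95% of random lists and called 100% of lists shifted 2-fold. The Hox test called 5% of simulations without a trend and 100% of those with one, over 38 genes. These rates check the code and do not carry over to the data. The simulated loci had an SD of 0.3 and no shift, while the real log2 ratio had an SD of 0.69 and a median of -0.38. The simulated lists had a smaller spread still. The simulated Hox trend was 1 fixed linear fall, and power for a trend of the observed size was not simulated. After a first run, the simulated lists were made more numerous and drawn from all loci of 1 RPKM or more, as fewer lists of higher loci had given a higher rate, and the SD was taken over higher loci, as the pseudocount shrank it over all. Alternatives covered the minimum, the pseudocount, filters, scaling, rows per locus and each replicate left out. Those chosen after seeing the data were CPM, protein-coding loci, single-identifier loci, matching on length, another random seed, Hox loci counted once, and 2-fold counts with the replicates rescaled to the same sum. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.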

Results

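Total RNA was sequenced from whole mouse embryos of CBA/Ca × C57Bl/10 crosses at embryonic day 10.5, a midgestation stage at which the heart beats and the limb buds and main brain divisions have formed. The series held 1 group with 2 replicates and no treatment, so it describes levels of transcripts in 1 kind of sample and holds no comparison between conditions. The labels do not say whether a replicate was 1 embryo or a pool. Summed over loci, the counts were 18318181 in replicate 1 and 117522171 in replicate 2, a ratio of 6.42. The library sizes implied by the authors' RPKM were smaller than these sums in both replicates, with a ratio of 5.68. Why the sums were larger was not tested, so they may not equal the number of reads. A count of 0 allowed up to 0.164 CPM (counts scaled to their sum over loci) in replicate 1 and 0.0255 CPM in replicate 2. Such limits cover counting error only, and with the smaller library sizes they would be higher. Of 34624 loci, 17090 (49.4%) reached 1 RPKM in both replicates, among them 12557 of 19295 protein-coding loci. A locus is 1 gene, or several overlapping genes that the authors joined, and values of joined loci cannot be given to 1 of their genes. Loci of a gene list passed, below, when they reached 1 RPKM in both replicates. Of the 51 gene lists, 17 had a median level above the middle 95% of random lists of their size and 2 lay below it.

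Globin transcripts of primitive red cells were abundant: all 3 embryonic and all 4 adult globin loci reached 1 RPKM in both replicates. The embryonic beta-type globin Hbb-y stood at 1746 RPKM in replicate 1 and 6474 in replicate 2, the embryonic alpha-type globin Hba-x at 1284 and 3219, and Hbb-bh1 at 1037 and 1920. Adult-type alpha globins stood in the same range, with Hba-a1 at 1054 and 4619 and Hba-a2 at 570 and 2694, while the adult beta globins were far lower, Hbb-b1 at 48.4 and 45.2 and Hbb-b2 at 46.4 and 29.1. Hbb-bh1 exceeded Hbb-b1 by 4.89 ± 0.70 on the log2 scale (SD, n = 2), beyond the replicate spread, whereas Hbb-y against Hbb-bh1 (1.25 ± 0.71) was within it and Hba-x against Hba-a1 changed sign between replicates (0.28 and -0.52). Near-identical globin copies share reads, so the split between Hba-a1 and Hba-a2 and between the adult beta genes is uncertain. All 19 measured loci of the list of erythroid regulators, membrane and heme genes reached 1 RPKM in both replicates, led by the transferrin receptor Tfrc (268 and 184), the heme synthesis enzyme Alas2 (131 and 60.3) and Hemgn (97.0 and 59.8), with Epor lowest (7.21 and 3.44). Of 12 haematopoietic progenitor loci, 10 reached the minimum: Meis1 (217 and 251) and Cd34 (47.4 and 48.8), both joined with other genes, and Lmo2 (27.0 and 16.8) were highest.

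Neural transcripts were abundant, and genes of progenitors and young neurons stood far above those of mature neurons and glia. All 15 neural progenitor loci reached 1 RPKM in both replicates, with a median of 49.7 and 29.4 RPKM. Nes, an intermediate filament of progenitors, was highest (284 and 318), followed by Fabp7 (203 and 277) and the joined locus of Zic1 and Zic4 (128 and 94.1). The 15 early neuron loci all reached the minimum too (median 52.5 and 49.9), led by the joined neurofilament locus of Nefm and Nefl (343 and 373), Map2 (197 and 189, joined) and Tubb3 (146 and 164). For mature neuron and synapse genes the median was 3.24 and 2.15 RPKM and 10 of 14 loci passed: the glutamate transporter Slc17a6 (9.11 and 9.28) and Snap25 (7.79 and 7.12) were among the 3 highest, and Slc17a7 was lowest (0.198 and 0.146). Glial genes passed at 4 of 10 loci, though 7 reached 1 RPKM in replicate 1 taken alone and 8 reached 0.3 RPKM in both replicates. The highest, Cnp (382 and 475), shares its locus with Dnajc7 and Nkiras2, so the value cannot be read as a glial transcript, and Mbp (8.15 and 4.84) and Olig1 (0.164 and 0.101, lowest) were lower. Nes exceeded the astrocyte filament Gfap by 7.82 ± 0.40 on the log2 scale (n = 2), beyond the replicate spread, while Sox2 against Tubb3 (-0.84 ± 0.02) was within it.

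Regional regulators of the nervous system were present at low to middle levels. Forebrain regulators passed at 8 of 10 loci, with Emx2 (58.9 and 63.2), Dlx1 (32.6 and 24.1, joined with an antisense gene) and Otx2 (28.2 and 18.1) highest and Rax lowest (1.28 and 0.615, joined). Midbrain and hindbrain regulators passed at 10 of 12 loci, led by the joined loci of Irx3 (21.4 and 17.2), Pax8 (10.4 and 4.74) and Pax5 (9.98 and 3.34), and Wnt1 was lowest (0.362 and 0.240). In the ventral spinal cord list 9 of 10 loci passed. Isl1 (30.8 and 16.9), the signal Shh (19.7 and 10.5, joined) and Sim1 (6.02 and 4.41) were highest, with Olig2 lowest (1.81 and 0.976). Neural crest genes passed at 12 of 14 loci, led by Ednrb (42.6 and 32.2), Twist1 (37.0 and 37.0) and Ets1 (42.1 and 31.3), and Dlx6 had 0 reads in both replicates.

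Contractile genes of the heart were expressed throughout the list fixed for them. All 23 cardiac loci reached 1 RPKM in both replicates, with a median of 32.3 and 29.8 RPKM: Myl4, an atrial myosin light chain, was highest (97.8 and 284, joined with other genes), then Actc1 (96.0 and 96.5) and Myh7 (74.4 and 94.2), and the early heart regulator Nkx2-5 was lowest (1.37 and 1.17). The cardiac actin Actc1 exceeded the skeletal actin Acta1 by 2.17 ± 0.02 on the log2 scale, and Nppa (41.8 and 46.0, joined) exceeded Nppb (5.79 and 6.05) by 2.70 ± 0.06, both beyond the replicate spread. Atrial Myl7 against ventricular Myl2 (-1.04 ± 0.77), Myh7 against Myh6 (0.17 ± 0.05) and Tnni1 against Tnni3 (-0.25 ± 0.28, Tnni3 joined) were within it, although Myl7 against Myl2 lay beyond it in replicate 2 alone (-1.59). Skeletal myogenic genes passed at 15 of 17 loci, with Myh3, the embryonic myosin heavy chain (37.1 and 29.5), Pax3 (39.4 and 25.8) and Des (22.8 and 19.9) highest and the muscle creatine kinase Ckm lowest (0.180 and 0.0632, joined). Pax3 exceeded Pax7 by 3.05 ± 0.08, Myog exceeded Myf6 by 1.66 ± 0.39 and Myf5 exceeded Myod1 by 1.26 ± 0.35, all beyond the spread, though in replicate 2 alone Myf5 over Myod1 (1.01) was not. Adult skeletal muscle genes passed at 7 of 12 loci, led by Mylpf (76.8 and 56.7) and the joined loci of Atp2a1 (29.2 and 26.9) and Casq1 (18.98 and 14.8).

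All limb bud loci passed, as did most loci of the facial, somite and cartilage lists. In the somite and presomitic list 13 of 20 loci passed. Meox1 (45.5 and 37.9), Meox2 (20.8 and 17.997) and Lfng (15.7 and 13.9) were highest, and Mesp1, a gene of nascent mesoderm, had 0 reads in both replicates. All 18 limb bud loci passed, led by Prrx1 (80.8 and 62.1), Gli3 (69.3 and 44.5) and Sall4 (38.5 and 20.04, joined). Tbx4, the hindlimb T-box gene, was the lowest of them (6.48 and 4.45), and its level and that of forelimb Tbx5 (7.46 and 5.48) differed by 0.21 ± 0.05 on the log2 scale, within the replicate spread. Pharyngeal and craniofacial genes passed at 14 of 16 loci, with Alx1 (45.2 and 30.9, joined) highest, followed by Dlx1 and Eya1 (21.7 and 14.4). Cartilage and bone genes passed at 7 of 13 loci: Col11a1 (107 and 99.1), Col2a1 (48.0 and 52.9) and Sox5 (47.4 and 44.9, joined) were highest and Matn1 was lowest (0.0473 and 0.0333). Col2a1 against Col1a1 (84.7 and 79.5, joined) lay within the spread (-0.69 ± 0.16).

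Endothelial genes passed at all 17 loci, with Egfl7 (95.9 and 87.5) and Eng (47.5 and 52.2), both joined, and Ramp2 (36.3 and 26.9) highest and Sox18 lowest (2.04 and 1.35). The epithelial list also passed at all 12 loci, led by Esrp1 (54.3 and 39.8, joined), Krt18 (53.4 and 31.9) and Epcam (15.7 and 22.5), with Krt14 lowest (5.48 and 3.41). N-cadherin, Cdh2 (139 and 109), exceeded E-cadherin, Cdh1 (11.8 and 7.12), by 3.61 ± 0.22, and the mesenchymal filament Vim (556 and 1094) exceeded Epcam by 5.30 ± 0.34, both beyond the replicate spread. Hepatic genes passed at 12 of 18 loci. The fetal serum protein Afp (196 and 82.0), Ttr (129 and 34.9, joined) and the apolipoprotein Apoa1 (141 and 19.7) were highest, and Apoc3 was lowest (0.619 and 0). Afp exceeded Alb (13.8 and 17.7) by 2.94 ± 1.12, beyond the spread. Adult liver genes passed at 1 of 14 loci, Arg1 (26.6 and 18.8). Saa1 (0.363 and 1.31) and Tdo2 (0.722 and 0.307) followed, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was lowest (0 and 0.0327). Gut, lung and pancreas regulators passed at 8 of 15 loci, led by the joined loci of Onecut1 (38.9 and 24.0), Shh and Gata6 (16.7 and 8.68), and Pdx1 was lowest (0 and 0.0339). Kidney and gonad regulators passed at 12 of 14 loci, with Emx2, Eya1 and Osr1 (18.9 and 16.0) highest and Sry, the testis-determining gene, lowest (0 and 0.0684).

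**Figure D1:**
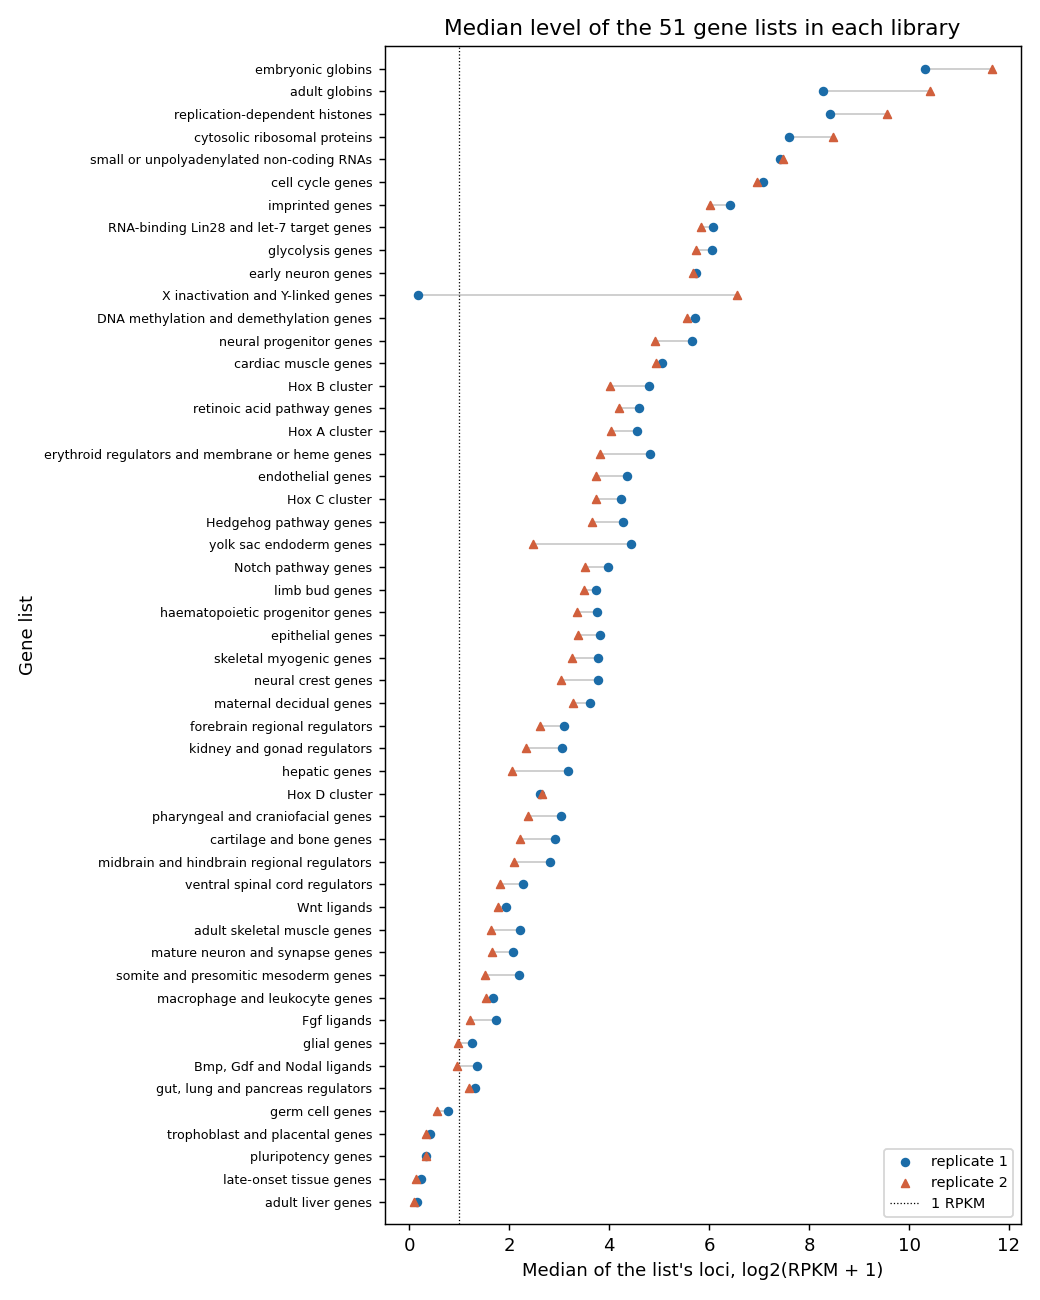
Median log2(RPKM + 1) over the loci of each of the 51 gene lists, with replicate 1 as circles, replicate 2 as triangles and a dotted line at 1 RPKM. Globins, histones and ribosomal proteins lie at the top, adult liver and late-onset genes are ordered last, and the list of X inactivation and Y-linked genes differs most between the replicates.

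Hox genes, whose order along each cluster follows the order of their domains along the body axis, were detected in all 4 clusters. Of 38 measured Hox genes in 33 loci, 35 reached 1 RPKM in both replicates. The highest were Hoxd3 (121 and 83.9, joined) and the joined loci of Hoxa2 and Hoxa3 (88.4 and 55.2) and of Hoxb2 and Hoxb3 (86.5 and 52.3). The lowest were Hoxc13 (0.408 and 0.299), Hoxc12 (0.466 and 0.601) and Hoxb13 (0.664 and 0.559), at the posterior end of their clusters. With each locus counted once per range, median RPKM was 54.8 and 32.2 for the 6 loci of paralogue groups 1 to 3, 26.5 and 15.2 for the 17 of groups 4 to 9, and 5.15 and 3.92 for the 11 of groups 10 to 13. The level of groups 1 to 3 rests on joined loci, as their 2 genes with a locus of their own, Hoxb1 (2.88 and 1.23) and Hoxd1 (4.01 and 3.06), were low. Across these genes, which are not independent replicates, Spearman's rho between paralogue number and log2(mean RPKM + 1) was -0.414 (two-sided permutation test within clusters, p = 0.0125). The 10 measured loci of cluster A all passed, 7 of 8 in cluster B, 6 of 8 in cluster C and 7 of 7 in cluster D. Taken alone, cluster C had rho -0.686 (permutation p = 0.0470, Benjamini-Hochberg adjusted over the 4 clusters 0.188), and clusters A, B and D had rho -0.314, -0.335 and -0.228 (adjusted permutation p 0.457, 0.457 and 0.589). The trend was not monotonic: besides Hoxb1 and Hoxd1, Hoxa10 stood out, at 40.0 and 29.6. With each of the 33 loci counted once, rho was -0.400 (permutation p = 0.0228). Only 22 of the genes had a locus of their own, and over these rho was -0.425 (permutation p = 0.0497).

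**Figure D2:**
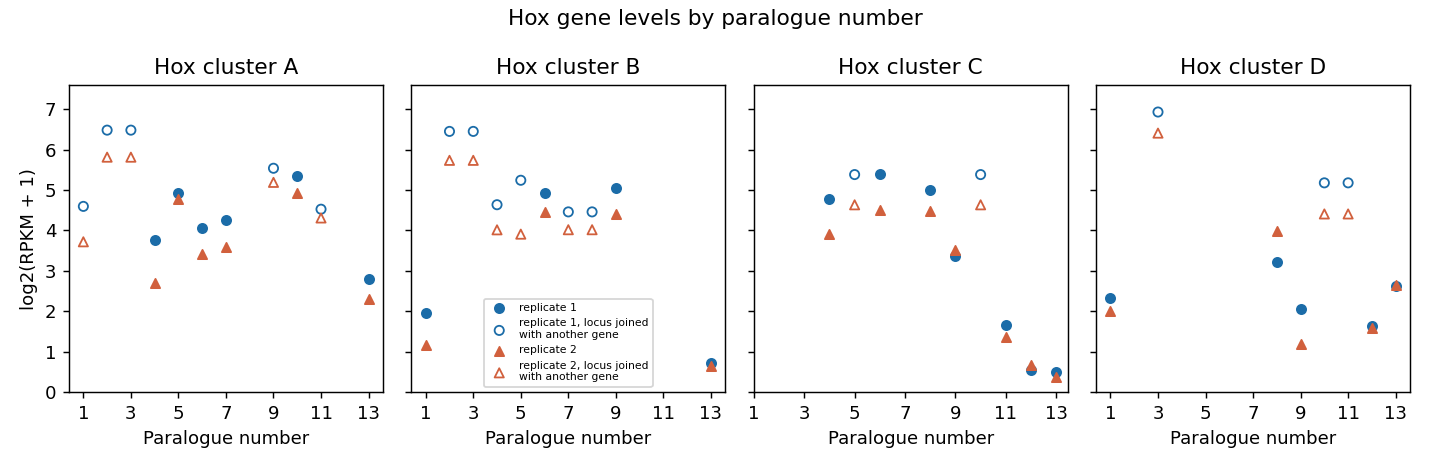
Levels of Hox genes as log2(RPKM + 1) against paralogue number in each cluster, with replicate 1 as circles and replicate 2 as triangles, and open symbols for loci that the authors joined with another gene. Paralogues 12 and 13 of cluster C lie near 0, while paralogues 2 and 3 of clusters A and B, in joined loci, are the highest of their clusters.

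Most loci of the pluripotency, germ cell, trophoblast and late-onset lists did not pass, while most loci of the decidual and macrophage lists did. Pluripotency genes passed at 4 of 14 loci, with Sall4, Lin28a (34.7 and 16.4, joined) and Tbx3 (20.7 and 12.7, joined) highest and Nanog lowest (0.0848 and 0.0238). Sall4 exceeded Pou5f1 (0.0650 and 0.423) by 4.55 ± 0.94, beyond the spread. Germ cell genes passed at 6 of 13 loci, led by Sycp3 (33.8 and 25.0, joined with Chpt1), Kit (23.7 and 14.5) and Tdrd7 (17.4 and 11.7), with Prdm14 lowest (0.0828 and 0.0437). Trophoblast and placental genes passed at 4 of 18 loci, though 7 reached 1 RPKM in replicate 1 taken alone and 8 reached 0.3 RPKM in both. Peg10 (151 and 66.1), which the embryo also expresses, Hand1 (7.06 and 3.37) and Prl2c2 (5.20 and 3.07) were highest, and Tpbpa and Psg21 had 0 reads in both. Maternal decidual genes passed at 8 of 10 loci, though the highest, Il11ra1 (103 and 145, joined with Ccl27a), Hoxa10 and Des, are not specific to decidua. Prl3c1 was the lowest (0.213 and 0.0209). Macrophage and leukocyte genes passed at 11 of 18 loci, led by Cd68 (13.4 and 8.96), Mrc1 (9.46 and 7.92) and Aif1 (7.22 and 4.01). Of 26 late-onset tissue loci 2 passed, Krt10 (11.99 and 6.09, joined) and Pomc (2.98 and 2.501), followed by Tg (0.711 and 0.687, joined). Tnp1, Prm2 and Gh had 0 reads in both replicates. The median levels of the adult liver and late-onset lists lay at percentiles 2.28 and 2.42 of random lists of the same size, close to the 2.5 edge.

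Imprinted genes were abundant, with a median of 84.8 and 64.2 RPKM and 31 of 32 loci passing. H19 (1526 and 5446), Nnat (386 and 1676) and Gnas (732 and 904), all joined with other genes, were highest and Ascl2 was lowest (0.136 and 0.0954). The maternally expressed H19 exceeded the paternally expressed growth factor Igf2 (151 and 96.4, joined) by 4.57 ± 1.75, beyond the replicate spread. Meg3, in a joined locus, against Dlk1 (0.68 ± 0.11) and Igf2 against Igf1 (1.07 ± 0.47) were within it, although Igf2 against Igf1 lay beyond it in replicate 1 alone (1.40) and with a pseudocount of 0.01. The 19 cell cycle loci all passed, with Top2a (713 and 1057, joined), Mki67 (582 and 633) and Ccna2 (255 and 301) highest and Plk1 lowest (72.7 and 57.6), and Ccnd1 against Ccnd2 differed by less than the spread (-0.26 ± 0.23). All 15 glycolysis loci passed, led by Pkm (374 and 579), Ldha (279 and 394) and Gapdh (144 and 278), with Hk1 lowest (28.7 and 20.8, joined). Ldha against Ldhb (2.14 ± 0.29, with 1.93 and 2.35 in the replicates) was within the wide spread of the highest level group, with its limit of 2.39. Slc2a1, in a joined locus, against Slc2a3 (0.51 ± 0.17) was within the spread at its level. Lin28 and let-7 target genes passed at all 10 loci, led by Igf2bp2 (140 and 119), Igf2bp1 (128 and 77.6) and Hmga2 (117 and 70.3, joined), with Trim71 lowest (13.4 and 4.36). Lin28b (90.1 and 67.4) exceeded Lin28a by 1.66 ± 0.44, beyond the spread. In the DNA methylation list 11 of 12 loci passed. Dnmt3a (281 and 363, joined), Uhrf1 (258 and 212) and Mbd2 (158 and 178) were highest and Dnmt3l lowest (0.391 and 0.0905, joined). Dnmt1 (121 and 139) exceeded Dnmt3b (24.9 and 20.9) by 2.46 ± 0.31 and Dnmt3b against Dnmt3a was -3.75 ± 0.43, both beyond the spread, while Tet1 against Tet2 (-0.65 ± 0.07) was within the spread.

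Signalling genes ranged widely. Hedgehog genes passed at 12 of 14 loci, led by Gli3, the receptor Ptch1 (54.1 and 40.0) and Smo (47.9 and 33.4), and Shh exceeded Ihh (0.349 and 0.192), the lowest, by 3.602 ± 0.47, beyond the spread, with Shh in a joined locus. Notch genes passed at 17 of 18 loci, with Dll1 (96.7 and 82.6, joined), Hes1 (79.0 and 71.6) and Jag1 (61.5 and 51.7) highest and Hes7 lowest (0.891 and 0.272, joined). All 14 retinoic acid loci passed, led by the binding proteins Crabp2 (476 and 730) and Crabp1 (239 and 289) and by Rarb (37.7 and 29.1), with Cyp26c1 lowest (2.73 and 1.22). The synthesis enzyme Aldh1a2 (28.3 and 21.2) exceeded the degrading enzyme Cyp26a1 (5.35 and 3.07) by 2.33 ± 0.17, beyond the spread, and Crabp1 against Crabp2 was within the spread (-1.16 ± 0.24). Fgf ligands passed at 14 of 22 loci, with Fgf2 (31.0 and 17.5, joined), Fgf13 (17.7 and 15.1) and Fgf20 (19.6 and 12.5, joined) highest and Fgf23 lowest (0 and 0.0290). Wnt ligands passed at 14 of 19 loci, led by Wnt5a (51.6 and 31.8, joined), Wnt5b (12.9 and 10.9) and Wnt7b (13.5 and 9.61, joined), with Wnt10a lowest (0.420 and 0.148). In the list of Bmp, Gdf and Nodal ligands 12 of 24 loci passed, led by the joined loci of Bmp5 (56.5 and 47.5) and Bmp8b (48.7 and 48.3) and by Gdf11 (31.4 and 26.4), and Lefty2 was lowest (0 and 0.0217).

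The replicates were then compared with each other, to give the error of these values. Across 18335 loci with a mean of 1 RPKM or more, Pearson's r of log2(RPKM + 1) was 0.956 and Spearman's rho was 0.963 (across loci, which are not replicates), and the SD of the log2 ratio was 0.69. Among the 13082 protein-coding loci r was 0.976 and the SD was 0.48. The median log2 ratio of replicate 2 over replicate 1 was -0.38, and list differences below are given relative to it. A change of 2-fold or more was seen at 556 loci that were higher and 1602 that were lower in replicate 2. Relative to the median shift the split turned, with 1043 higher and 577 lower, and with the replicates rescaled to the same sum 156 were higher and 11260 lower. With 1 library on each side these differences have no replicate check and no p-value.

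**Figure D3:**
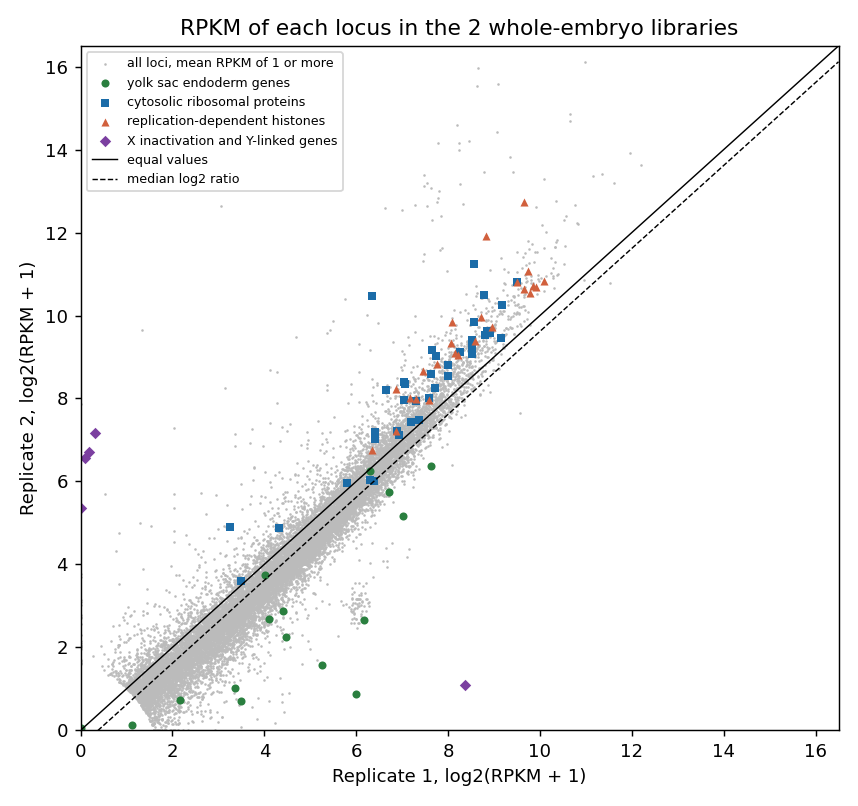
Each point is a locus with a mean of 1 RPKM or more, placed by log2(RPKM + 1) in replicate 1 and replicate 2, with 4 gene lists coloured, a solid line at equal values and a dashed line at the median log2 ratio of -0.38. Ribosomal protein and histone loci lie above the dashed line, most yolk sac endoderm loci below it, and Xist and the Y-linked genes at opposite corners.

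Sex-chromosome transcripts were among those that differed most between the libraries, and 1 of the 5 loci of the X inactivation and Y-linked list reached 1 RPKM in both. The locus that joins Xist, the RNA that coats the inactive X chromosome, with its antisense Tsix stood at 330 RPKM in replicate 1 and 1.15 in replicate 2. The Y-linked genes Eif2s3y (0.244 and 143), Uty (0.131 and 104), Ddx3y (0.0706 and 93.1) and Kdm5d (0 and 39.8) went the other way. Among the 10 loci with the largest ratio toward replicate 2 stood the RNase P-related RNAs Rprl3 (7.29 and 6428) and Rprl2 (1.51 and 805), and spliceosomal RNA Rnu2-10 (397 and 47569). Toward replicate 1 stood the lipoprotein gene Apob (71.1 and 5.30), the joined loci of Apoa4 (62.6 and 0.842) and of the endocytic receptor Cubn (37.4 and 1.98), and Trap1a (22.05 and 0.868).

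Yolk sac endoderm, hepatic and erythroid genes were lower in replicate 2 than in replicate 1 relative to the median shift. Of 16 yolk sac loci 11 passed the minimum, and the list's median log2 ratio lay -1.10 from that of all loci, with 13 of 16 loci below it. Afp, Ttr and Trf (104 and 52.8, joined) were its highest members and Npc1l1 was the lowest (0 and 0.0353). The hepatic list, which shares Afp and Ttr with it, lay at -0.61, with 15 of 18 loci below the median shift, and the erythroid list at -0.51, with 17 of 19. The Lin28 list lay at -0.16, below the middle 95% of random lists matched on level. Higher in replicate 2 relative to the shift were the adult globins (1.40), cardiac genes (0.26) and macrophage genes (0.30). The adult globin value came from Hba-a1 (2.51) and Hba-a2 (2.62), as Hbb-b1 lay at 0.29 and Hbb-b2 at -0.27. In the X inactivation and Y-linked list (median 6.84) the 4 Y-linked loci were higher and the locus of Xist lay at -6.89. Without the shift removed the cardiac and macrophage medians had the other sign (-0.12 and -0.08). In all, 11 of the 51 lists lay outside the middle 95% of their matched random lists, against 2.55 expected for lists of randomly drawn loci. Members of a list may vary together and some lists share genes, so that number is no measure of chance between 2 libraries. The Lin28 list lay inside in CPM. The Lin28, cardiac and macrophage lists lay inside when random lists were matched on length in place of level, where 22 lists lay outside. Level was then not matched, so lists gained or lost in that setting cannot be put down to length alone. Newly above their range with length matched were embryonic globins (1.71), early neuron, cell cycle, imprinted and late-onset genes. Of the 26 late-onset loci, 24 lay below 1 RPKM in both replicates. There the pseudocount holds the log2 ratio near 0 (list median -0.014), which lies above a negative shift. Over its loci with a mean of 1 RPKM or more, that list lay at -0.15 relative to the shift, inside its range matched on level. Newly below were the Hox A, Hox B, midbrain and hindbrain, ventral spinal cord, limb bud, kidney and gonad, Fgf, Hedgehog and Notch lists. In CPM embryonic globins lay above (2.09), and the trophoblast and Hedgehog lists below.

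**Figure D4:**
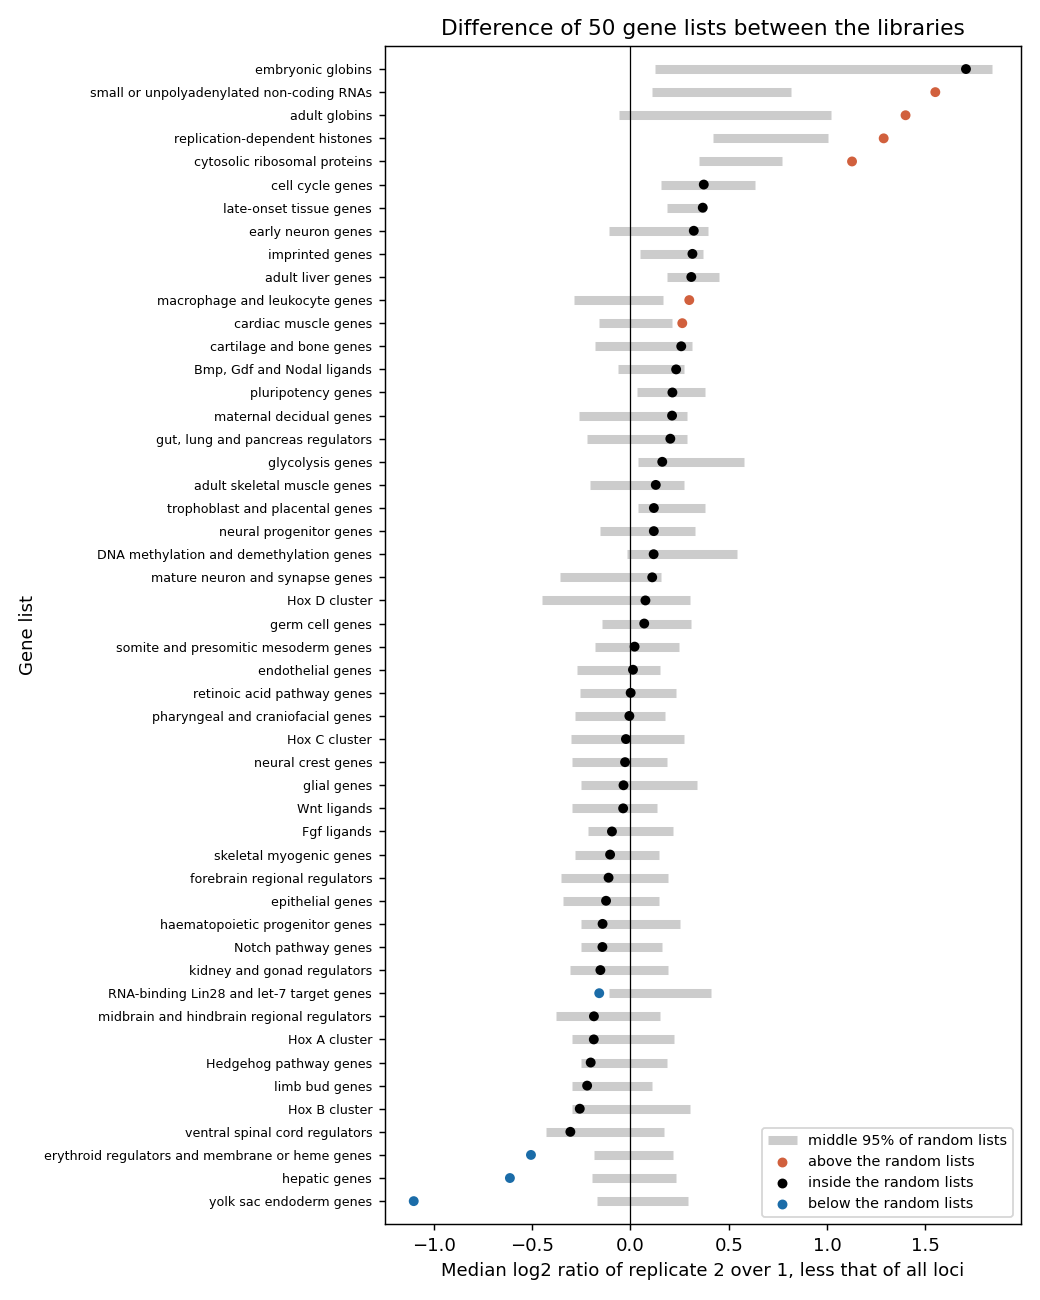
Median log2 ratio of replicate 2 over replicate 1 for 50 gene lists, less the median of all loci, as points, with grey bars for the middle 95% of random lists matched on level, and without the X inactivation and Y-linked list (6.84). Yolk sac endoderm genes lie lowest at -1.10, embryonic globins lie highest but within their bar, and small non-coding RNAs, adult globins, histones and ribosomal proteins lie above theirs.

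Abundant short and non-polyadenylated transcripts made up more of replicate 2. The 20 protein-coding loci with the highest mean RPKM also all lay above the median shift, by 0.98 to 3.48. That mean includes replicate 2, which favours loci that are higher there. Histone and globin loci and the joined locus of Rmrp are among the 20, so they say little about a rise in other transcripts. Small-RNA loci as a whole did not rise, as the median of the 1266 with a mean of 1 RPKM or more lay -0.31 from the shift. Before the shift was removed, 437 of them were 2-fold lower and 108 were 2-fold higher in replicate 2. Loci annotated as small RNAs took 0.552% of the reads in replicate 1 and 6.63% in replicate 2, and the 10 highest loci took 2.83% and 20.8% of the summed RPKM, while the 10 loci with the most reads took 3.09% and 9.11% of the reads. Rn7sk, a regulator of transcription elongation, had the highest mean (2034 and 70834), although Gm10800 was higher in replicate 1 (4733). The list of small or unpolyadenylated RNAs passed at 12 of 13 loci and lay 1.55 above the median shift. After Rn7sk its highest members were the joined loci of Malat1 (2597 and 10964) and Rmrp (959 and 6288). The lowest was Rpp25 (0.496 and 0.454), a protein-coding gene and not an RNA of this kind. All 24 histone loci passed, led by Hist1h4d (799 and 6836), Hist1h2bb (455 and 3866) and Hist1h1c (853 and 2143), with Hist1h3a lowest (80.2 and 107), and the list lay 1.29 above the shift with all 24 loci above it. All 38 ribosomal protein loci passed and all 38 lay above the shift (median 1.13). Rplp1 (378 and 2423), Rpl4 (722 and 1791) and the joined locus of Rps3 (439 and 1432) were highest, and Rps29 was lowest (10.3 and 11.02). Histone genes and ribosomal protein genes have near-identical copies and pseudogenes, so values of single members are uncertain. Of the 20 loci with the highest mean RPKM 2 were protein-coding, Gm10800 (4733 and 12756) and the translation factor Eef1a1 (3127 and 9436), and 8 had an identifier with no symbol. That ranking follows replicate 2: among the 20 highest of replicate 1 alone 7 were protein-coding, and of replicate 2 alone 1.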

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

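The CPM, protein-coding, single-identifier, length-matched and other-seed settings, the 2-fold counts at the same sum, and Hox loci counted once, were chosen after the data were seen. The number of loci at the minimum, the list members at it, the lists above the upper edge of level, and the Hox trend stayed within 1.5 times the main count, or kept their sign and side of the threshold, under each setting run for them. The share of the summed RPKM in the 10 highest loci rests on the replicate, at 2.83% without replicate 2 and 20.8% without replicate 1. For the Hox trend Spearman's rho ranged from -0.457 to -0.367 (permutation p from 0.00564 to 0.0497), and Pearson's r was -0.492 and -0.4997 with pseudocounts of 1 and 0.1 (permutation p = 0.00323 and 0.00237). The SD of the log2 ratio between replicates was 0.86 and 0.96 with pseudocounts of 0.1 and 0.01, 0.55 with no filter, 0.74 at a mean of 10 RPKM or more, 0.64 with replicates rescaled to the same sum, 0.72 with a median ratio of 0, 0.59 in CPM and 0.48 for protein-coding loci. In that order Pearson's r was 0.945, 0.932, 0.976, 0.911, 0.952, not changed beyond its bootstrap interval, 0.964 and 0.976, and Spearman's rho moved with no filter (0.947), at 10 RPKM (0.924), in CPM (0.971) and for protein-coding loci (0.981). Loci 2-fold higher in replicate 2 numbered 156 with replicates rescaled to the same sum, 1118 with a median ratio of 0, 303 in CPM and 149 among protein-coding loci. Loci 2-fold lower numbered 2693 and 2836 with pseudocounts of 0.1 and 0.01, 474 at 10 RPKM, 11260 with replicates rescaled to the same sum, 730 with a median ratio of 0 and 601 among protein-coding loci, where fewer loci were counted. Lists below the lower edge of level numbered 4 with random lists from loci above 0 or from protein-coding loci and 1 with another random seed, and 1 to 1 with a replicate left out. The pluripotency and trophoblast lists were the ones added when random lists came from loci above 0 (percentiles 1.16 and 2.08) or from protein-coding loci (0.67 and 0.93). Lists outside the matched range numbered 22 when matched on length in place of level. Pairs beyond the spread numbered 11 of the 21 pairs in loci of their own. Except where the construction shows it, the cause was not tested. Over 5 settings, the 11 lists called on the replicate ratio kept that call in 51 of 55 cases and lost it in 4, and other lists gained one in 18 of 200 cases. List members at the minimum moved beyond 1.5 times in 32 of the settings run per list and not in 223. Relative to each setting's own median, none of these 11 lists changed sign, and no pair called beyond the spread in the main analysis did. No paired analysis was possible because the series has 1 group. The depth of replicate 1 limits the low genes, and lists compared between replicates have no setting without a replicate.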

Other observations

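The tests of abundant small RNAs alone, by either selection, of a length trend as the whole cause, of liver through Alb, and of pools of both sexes were chosen only after the result was seen. The labels name no biological difference between the replicates, so no biological explanation from the design was tested.

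Small RNAs did not move as 1 class. Among loci selected on replicate 1 alone, which works against higher values in replicate 2, all 14 small-RNA loci at 300 to 1000 RPKM were higher in replicate 2 relative to the median shift (median log2 ratio 4.87), and so were 22 of the 30 at 100 to 300 RPKM (1.22). Among loci selected on replicate 2 alone, which works against lower values there, 259 of 371 at 3 to 10 RPKM were lower (-0.43), among them 97 of 116 spliceosomal RNA loci (-0.72). These groups were chosen after values were seen. Copies of these RNAs share sequence, so their reads cannot be given to single loci.

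Abundant small and short RNAs were higher in replicate 2, and the test of the authors' length scaling, written for all small-RNA loci, was first run, in error, with a limit of 100 RPKM. As written, the median log2 ratio in CPM, less that of all loci, was -0.56 (n = 1266): this met the limit set in advance for length scaling as the cause (below 0.5), but it is read as open, a condition added after the value was seen, because these loci do not show the pattern in RPKM either (-0.31). The first run, over the 67 loci with a mean of 100 RPKM or more, gave 2.20 (bootstrap interval 1.78 to 2.81), against 2.12 in RPKM. A later selection of the 47 with 100 RPKM or more in replicate 1 gave 1.81. At single-transcript loci the reads per RPKM had 1 ratio between replicates (5.68), so the length cancels when replicates are compared. For such loci CPM had to repeat the RPKM difference, so these runs could not test length scaling. The constant ratio itself leaves length scaling no part in the difference there. How many of the small-RNA loci are single-transcript was not counted. A length trend is argued against as the whole cause, as ribosomal proteins, histones and the small RNA list still lay 1.01, 1.18 and 1.63 above loci of their length (bootstrap intervals from 0.801, 1.06 and 0.788 up). These 3 values were not matched on level. A part from length-dependent recovery of fragments stays open. Over 10896 protein-coding loci of 1 kb or more, rho between implied length and the log2 ratio was -0.0921 (interval -0.111 to -0.0759). The limits were -0.2 for it and -0.1 against it. That test left out shorter loci, where the trend was stronger. In the shortest groups of protein-coding loci, of median length 0.54, 0.75 and 0.89 kb, the median ratio lay 0.27, 0.17 and 0.10 above the shift. In the longest group (6.81 kb) it lay at -0.05. GC content stays open too, with rho -0.137 against the length-corrected ratio, between the limits of 0.1 and 0.2 in size.

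Yolk sac endoderm genes were higher in replicate 1. A length trend does not account for this, as the list's length-corrected median over 14 loci was -1.42 (bootstrap interval below -0.90). Without the correction the same 14 loci lay at -1.31 relative to the shift. Yolk sac endoderm tissue in replicate 1 is a candidate explanation that stays open: a second list that shares no gene with the first had a median of -0.78 relative to all loci over 28 members, between the limits of -1 and -0.5 set in advance, and 25 of the 28 lay below the median shift. Its highest members, Apoe (167 and 123 RPKM), Slc39a8 (90.6 and 44.5) and Slc16a1 (75.96 and 51.9), lay -0.06, -0.63 and -0.16 from that shift, Hnf4a had been seen in the hepatic list, and liver, gut and kidney express many of these genes. More liver tissue in replicate 1 stays open as well, though Alb, the 1 gene of its test, went against it. Alb lay 0.72 above the median shift, where liver required a value well below the shift and the limit against liver was at or above it. By counting error alone this would have argued against liver. The spread of loci of its level (SD 0.51), taken as the yardstick after its value was seen, gives an interval of -0.28 to 1.72. The hepatic list, which shares Afp and Ttr with the yolk sac list, went the other way, at -0.61 relative to the shift.

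Xist and Y-linked genes were opposite in the libraries. Pools of both sexes in both libraries are argued against, as the 4 Y-linked genes gave 11 reads in replicate 1 and 60385 in replicate 2, and their CPM in replicate 1 was 0.117% of that in replicate 2. The joined locus of Xist and Tsix had 42407 reads in replicate 1 and 922 in replicate 2, where its CPM was 0.339% of that in replicate 1. A candidate explanation is that each library came from embryos of 1 sex, female in replicate 1 and male in replicate 2. The read counts above are what this would give, and sex could then not be told apart from replicate. Genes that escape X inactivation had a median of -0.39 relative to all loci, past the limit of -0.3 set in advance. The interval over these 7 genes, -0.65 to 0.08, includes 0, 5 of the 7 lay below the median shift, and Ddx3x, singled out after its values were seen, went the other way (799 and 1399.6 RPKM). X-linked protein-coding loci did not differ detectably from autosomal ones (0.01 on the log2 scale, interval -0.03 to 0.06), and the number of embryos behind each library remains unknown.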
